A study of Danio rerio with 24 samples.

How the data were processed

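Total RNA of 20 zebrafish embryos (AB/TL) per sample was amplified, coupled to Cy3 or Cy5 and hybridised with a common reference to 2-colour Agilent arrays of 180822 spots, 4 arrays on each of 6 slides, per the labels' protocols and the file headers. Every slide was scanned in a batch of its own, so that slide and scan were one factor. Injection, treatment and experiment number were taken from the labels, and the 3 replicates of a group came from separate experiments, per the labels. The labels write the dexamethasone dose as 100 mM, and they call the treatment at 24 h both an injection and a treatment. The unit was left as written.

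The scanner files hold mean spot and median background intensities, which are not normalized, per the file headers. They also hold Agilent's log10 ratio of Cy5 over Cy3, which Feature Extraction 10.7.3.1 had background-subtracted and dye-normalized, per the file headers. The submitters' processing notes name versions 9.5.3.1 and 9.5 instead. The authors' deposited value table has log10 values equal to that ratio, with a largest difference of 0 and a median of 0 on every array, and no further scaling or centring. Its direction is thus Cy5 over Cy3. The log2 values analysed were computed from the deposited intensities.

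Intensities were corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, and normalized within each array by loess with control spots at weight 0. Flagged outlier spots were left out, between 17 and 166 per array, and no spot was saturated. Probes entered the tests where Cy3 was well above background on at least 3 arrays and each group had at least 2 unflagged values, which kept 147568 of 175974 probes. All probes were 60 bases long. Probes that shared any 30 bases in a row exactly, on the same strand, were joined into 158815 overlap groups by a search of their sequences. Shorter or inexact matches were not joined, so probes of different groups can read 1 transcript.

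The ratio was taken as Cy3 over Cy5, with Cy3 as the sample. The design fixed before the data were examined had Cy5 as the sample, as the labels say. It was turned after the channels were seen, because the values that follow the groups lie in Cy3 and the values of a common reference should not. First fits had been run with the labelled direction and a filter on Cy5. The alternative with the dyes as labelled was added for that reason.

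Groups were compared with lmFit and eBayes on 8 group means over all 24 arrays, with 16 residual degrees of freedom. The contrasts were dex over all 4 injections, dex within each injection, each injection against SC-MO in vehicle, each injection's response minus that of SC-MO, and an F-test over the groups. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. On simulated data of 147568 probes and 24 arrays, changed at 50 probes per size, the contrast dex in SC-MO recovered 18% of log2 changes of 0.5, 82% of 1, 98% of 2 and 100% of 4, with 9 false calls. Replicate arrays of a group correlated at 0.259 to 0.612 in log ratio. Their smallest median absolute difference was 0.14, against 0.07 between probes of identical sequence on one array, so no 2 arrays were counted as one.

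The rule for named features, fixed before the data were examined, took genes by symbol, by the largest changes and by membership of gene lists. The files pair no probe with a gene, and a probe was never named from its sequence or ID. The gene lists, their tests, the mean over probes of a gene and the check of the receptor's transcript were therefore not run. In their place, chosen after the data were seen, the text names at most 2 probes that rose and 2 that fell per contrast, those with the largest change and from different overlap groups. LOLT00996 and the contrast of MO2 against MO1 were added after their values were seen.

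Alternatives fixed before the data were examined were no background subtraction, Agilent's ratio, the authors' value table, scaling between arrays, 2 other filters on dim probes, slide as a fixed or random block, a replicate block, a fit of only the groups compared, and leaving out each array. The dyes as labelled and 1 probe per overlap group were added later. Scan date as a block equals slide as a block and was not run separately. Chance was tested by redrawing the arrays into groups of the same sizes, with probes that could not be fitted in a redraw counted as not called. For the differences between responses the labels were first redrawn within each injection. After that result was seen, relabelings that only exchange dex and vehicle everywhere were merged, and a free redraw of the 12 arrays was added. Slide differences were read on probes called without the 2 arrays of that slide. Unchanged groups against shared arrays were simulated in 100 sets for correlations and 20 for counts of calls.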

Results

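Transcript levels were measured in whole zebrafish embryos in which signalling through the glucocorticoid receptor (GR), the nuclear receptor that binds cortisol and the synthetic glucocorticoid dexamethasone, had been altered by injection soon after fertilisation. The injected materials were a standard control morpholino (SC-MO), a morpholino that lowers both receptor isoforms, α and β (MO1), a morpholino that moves splicing towards the β isoform (MO2), and mRNA of the zebrafish β isoform (zGRb mRNA). Morpholinos are stable antisense oligomers, and all 3 were given at 0.05 mM in 1 nl. The zGRb mRNA was given at a concentration that the labels write as 5 ng/ml, also in 1 nl. Each injection was followed at 24 h post-fertilisation by 6 h in dexamethasone (dex), at a concentration that the labels write as 100 mM, or in vehicle (veh). The 8 groups held 3 arrays each, from 3 separate experiments, and every array carried RNA of 20 embryos beside a common reference, a pool of all the study's RNA. Over the 24 arrays the median spot intensity lay between 186 and 277 in Cy3 and between 224 and 319 in Cy5, against median backgrounds of 28 to 39 and 50 to 57. Between 61.7% and 81.2% of probes were well above background in Cy3, and the number of arrays limits the precision. The files pair no probe with a gene, so probes are named by their array ID alone, and the level of the receptor's own transcript was not analysed here.

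The direction of every ratio rests on the channels. The labels put the common reference in Cy3 and the embryos' RNA in Cy5, but the signal that followed the groups lay in Cy3. The moderated F-test of limma over the 8 groups called 9207 probes on Cy3 intensities alone and 2 on Cy5 intensities alone. Of the probes called on the ratios, 99.3% varied more over the arrays in Cy3 than in Cy5. Cy3 also varied more over all tested probes, with a median SD of 0.245 against 0.131 in Cy5. The 99.3% alone therefore does not show that Cy3 followed the groups. Probe A_15_P100902 read 9.5 ± 0.18 (log2 intensity, SD, n = 3) in Cy3 on the SC-MO/veh arrays and 16.24 ± 0.26 on the SC-MO/dex arrays, while its Cy5 value was 15.00 on both. All log2 ratios here are therefore Cy3 over Cy5, with Cy3 taken as the sample. This direction opposes the labels and was chosen after the data were seen. With the dyes as labelled every sign turns, so that each "higher" becomes "lower", and dex in SC-MO, with the filter on dim probes then set on Cy5, gave 50 higher and 660 lower probes.

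**Figure D1:**
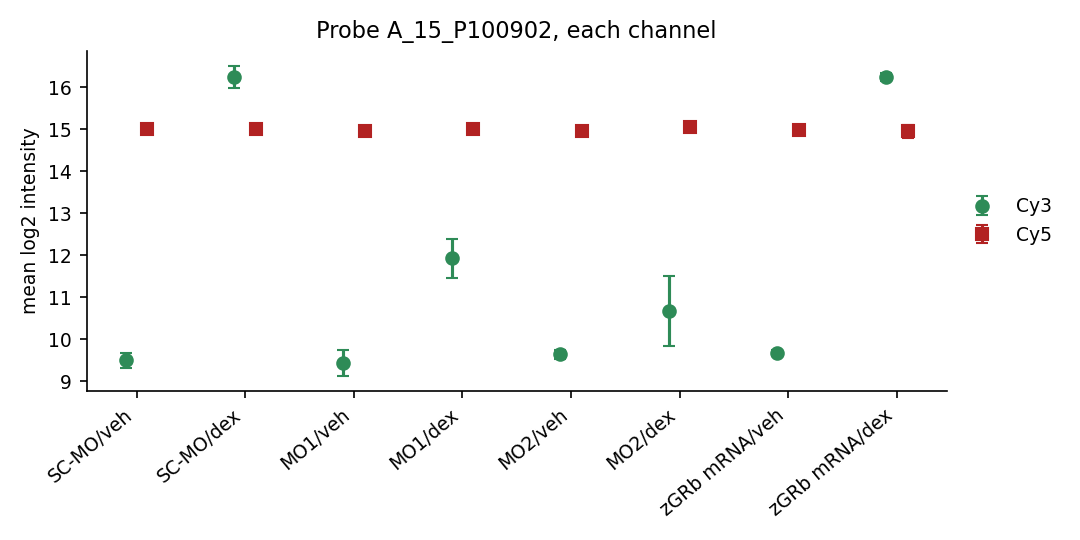
Mean log2 intensity (y axis) of probe A_15_P100902 in each of the 8 groups (x axis), for Cy3 (circles) and Cy5 (squares), with bars of 1 SD over 3 arrays. Cy5 stayed close to 15.00 in every group, and Cy3 ranged from 9.44 in MO1/veh to 16.24 in SC-MO/dex and zGRb mRNA/dex.

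The groups differed at 13716 of the 147568 tested probes (limma's moderated F-test, Benjamini-Hochberg adjusted p under 0.05), and at 8327 with slide as a fixed block. Averaged over the 4 injections, dexamethasone raised 905 probes and lowered 48. The largest mean rise was 4.35 ± 0.14 (log2, SE) at A_15_P100902, with adjusted p = 2.54e-13, and the largest mean fall was -1.26 ± 0.14 at MAD_Dr_004_194275-1, with adjusted p = 1.38e-05. This average joins injections whose responses differed, as given for each one. With slide as a fixed block the average effect called 686 probes, 671 of them higher and 15 lower, and the 48 were 27 without MO1/dex replicate 1, 28 without SC-MO/veh replicate 3, and 31 without MO2/dex replicate 2, MO1/dex replicate 3 or MO1/veh replicate 1.

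**Figure D2:**
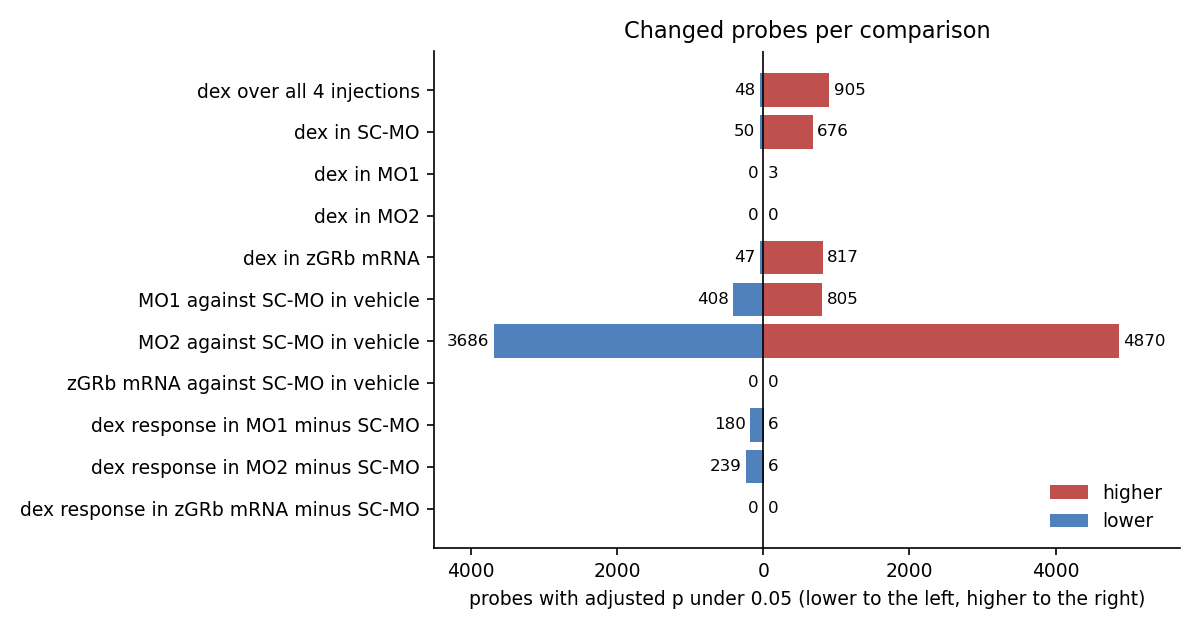
Number of probes (x axis) higher, to the right, or lower, to the left, at an adjusted p under 0.05 in each comparison (y axis), from limma on 147568 probes and 24 arrays. MO2 against SC-MO in vehicle had the most, 4870 higher and 3686 lower, and 3 comparisons had none.

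The response to dexamethasone in control-injected embryos was almost entirely a rise. In SC-MO embryos 676 probes rose and 50 fell, and 364 of the risers and 20 of the fallers changed at least 2-fold. The risers fell into 550 groups of overlapping probe sequence. Probe A_15_P100902 (60-mer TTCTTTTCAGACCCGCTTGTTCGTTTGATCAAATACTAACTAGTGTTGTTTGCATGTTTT) had the largest rise, 7.01 ± 0.29 (log2, SE), or 129-fold, from a mean log2 ratio of -5.14 ± 0.09 (SD, n = 3) to 1.87 ± 0.30, with adjusted p = 9.68e-12. MAD_Dr_004_148407-1 (60-mer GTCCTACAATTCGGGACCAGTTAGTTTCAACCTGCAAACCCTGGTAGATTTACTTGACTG) rose by 6.80 ± 0.27, or 112-fold, with adjusted p = 6.22e-12. The largest falls were smaller, -2.06 ± 0.28 at MAD_Dr_004_194275-1 (adjusted p = 0.000253) and -1.84 ± 0.40 at MAD_Dr_004_159104-1 (adjusted p = 0.0353). The call of MAD_Dr_004_159104-1 was lost under 11 of 34 alternatives, among them Agilent's ratio, slide as a fixed block and the replicate block but not slide as a random block, with values of -1.99 to -1.66 over the 34. Taken over the 676 risers, the array medians were 0.58 to 0.75 on the 3 SC-MO/dex arrays and -0.49 to -0.41 on the 3 SC-MO/veh arrays. The vehicle and dex arrays of SC-MO shared no slide, so no difference within a slide can be given. With slide as a fixed block 251 probes were higher and 7 lower. The median size of the change over the 726 was 1.03 without and with the block, while the SE of a probe of median precision went from 0.15 to 0.19. Without SC-MO/dex replicate 3 the count was 466, and the 50 fallers were 11 without that array, 17 without SC-MO/veh replicate 3 and 21 without SC-MO/veh replicate 2.

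In embryos given zGRb mRNA the response had the same form. Dexamethasone raised 817 probes and lowered 47, and 572 of the risers and 30 of the fallers were also called in SC-MO, where independent lists would share 3.74 and 0.0159. A_15_P100902 rose by 6.93 ± 0.29 (log2, SE; adjusted p = 1.27e-11) and MAD_Dr_004_148407-1 by 6.81 ± 0.27 (adjusted p = 4.54e-12), while MAD_Dr_004_194275-1 fell by 2.17 ± 0.28 (adjusted p = 0.000121) and MAD_Dr_004_171325-1 fell by 1.502 ± 0.334 (adjusted p = 0.0413). The call of MAD_Dr_004_194275-1 was lost with slide as a fixed block, at -1.96 ± 0.38. The call of MAD_Dr_004_171325-1 was lost under 13 of 34 alternatives, among them Agilent's ratio, slide as a fixed block and the replicate block, with values of -1.62 to -1.40 over the 34. Over all tested probes the responses in SC-MO and zGRb mRNA had r = 0.581 (0.361 with Agilent's ratio) and rho = 0.214, a correlation across probes, which are not independent replicates. The test of the difference between the responses in zGRb mRNA and in SC-MO called 0 probes (limma), with 1742 at an unadjusted p under 0.05, and A_15_P100902 differed by -0.09 ± 0.41. For a probe of median precision the SE of this difference was 0.21, so a difference that misses the threshold does not show equal responses. The 1742 were fewer than the 7378 expected with no effect, and the fit paired no dex array with a vehicle array. With slide as a fixed block 350 probes were higher with dex in zGRb mRNA and 8 lower, and the median size of the change over the 864 was 0.99 without and 1.04 with the block. The 47 fallers were 18 without zGRb mRNA/veh replicate 1, 28 without zGRb mRNA/veh replicate 3, 22 without zGRb mRNA/dex replicate 2 and 19 without zGRb mRNA/dex replicate 3.

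The response was small or undetected in the 2 receptor morpholino groups. With MO1, dexamethasone raised 3 probes and lowered 0 (limma; 1056 probes at an unadjusted p under 0.05), and the largest rises were 2.52 ± 0.29 at A_15_P100902 and 2.23 ± 0.27 at MAD_Dr_004_148407-1, both with adjusted p = 0.00455. The other called probe was LOLS12843, 2.019 ± 0.275 (adjusted p = 0.0223). The end of LOLS12843 matches the start of MAD_Dr_004_148407-1, so both can read the same transcript. The 3 calls were lost, with 0 probes left, when only the groups compared were fitted, without MO1/dex replicate 3, without MO1/veh replicate 2, or with the ratios scaled between arrays. Without MO1/veh replicate 3, 1 call was left, while A_15_P100902 read 2.28 to 2.96 over all 34 alternatives. With MO2, limma called 0 probes, with 3571 at an unadjusted p under 0.05, and A_15_P100902 read 0.96 ± 0.29 with adjusted p = 1. The 676 probes that rose in SC-MO had a median change of 0.12 in MO1 (quartiles 0.05 and 0.22), 0.05 in MO2 (quartiles -0.04 and 0.14) and 1.06 in zGRb mRNA (quartiles 0.72 and 1.51). A set chosen in SC-MO favours SC-MO. The 817 probes chosen in zGRb mRNA had median changes of 0.92 in SC-MO, 0.12 in MO1 and 0.04 in MO2. Neither MO1 nor MO2 had dex and vehicle arrays on one slide. The 1056 and 3571 probes at an unadjusted p under 0.05 were fewer than the 7378 expected with no effect, and the fit paired no dex array with a vehicle array, so these counts do not show that a response was absent.

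**Figure D3:**
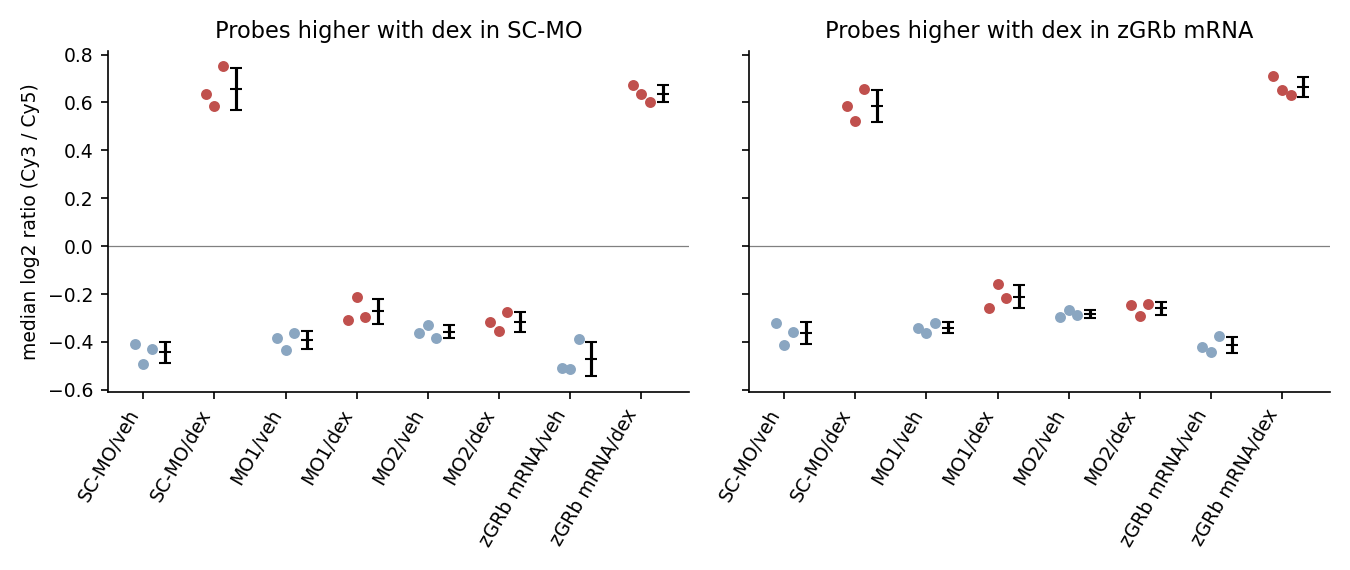
Median log2 ratio (y axis, Cy3 over Cy5) on each array of the 676 probes higher with dex in SC-MO (left) and of the 817 probes higher with dex in zGRb mRNA (right), by group (x axis). Points are arrays, and the bars beside them are the mean and 1 SD of 3 arrays. In the left panel the MO1/dex arrays lay between -0.31 and -0.21 and the SC-MO/dex arrays between 0.58 and 0.75.

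The difference between responses was itself tested. The response in MO1 was lower than in SC-MO at 180 probes and higher at 6, and the response in MO2 was lower at 239 and higher at 6 (limma interaction contrasts). All of these probes were among those called for dex in SC-MO, the lower ones among its risers and the higher ones among its fallers, and 168 of the lower ones were common to MO1 and MO2. Both contrasts subtract the response of the same SC-MO arrays, and the responses in MO1 and MO2 were small. This nesting and the shared 168 therefore follow largely from the contrasts and are no separate evidence. For MO1 the largest lower values were -4.68 ± 0.45 at A_15_P120582 (adjusted p = 1.55e-05) and -4.60 ± 0.39 at LOLS12843 (adjusted p = 2.65e-06). A_15_P120582 went from -2.60 ± 0.67 (SD, n = 3) to 2.00 ± 0.85 with dex in SC-MO, and read -3.09 ± 0.21 and -3.16 ± 0.02 in MO1/veh and MO1/dex. LOLS03383 and MAD_Dr_004_156884-1 had the largest higher values, 1.39 ± 0.20 (adjusted p = 0.00167) and 1.35 ± 0.22 (adjusted p = 0.00594). For MO2 the largest lower values were -6.05 ± 0.41 at A_15_P100902 (adjusted p = 7.61e-08) and -6.004 ± 0.376 at MAD_Dr_004_148407-1 (adjusted p = 2.74e-08), and the largest higher ones 1.37 ± 0.19 at MAD_Dr_004_102399-1 (adjusted p = 0.00106) and 1.36 ± 0.26 at MAD_Dr_004_501114-1 (adjusted p = 0.0291). The call of MAD_Dr_004_501114-1 was lost under 14 of 34 alternatives, among them Agilent's ratio, scaling between arrays, slide as a fixed block and the replicate block, with values of 1.18 to 1.55 over the 34, and the 6 higher probes for MO2 were 3 without MO2/veh replicate 3. SC-MO/dex and MO1/veh lay on slides 4 to 6 and the other groups of this contrast on slides 1 to 3. With slide as a fixed block 23 of the 186 and 51 of the 245 probes remained past the threshold, all lower. Over the 186 and the 245 the median size of the difference went from 1.48 to 1.46 and from 1.46 to 1.53 with the block, and for a probe of median precision the SE rose from 0.21 to 0.32 and 0.30. With the block A_15_P120582 read -5.16 ± 0.68 and LOLS12843 -3.52 ± 0.41 for MO1. For MO2 A_15_P100902 read -5.40 ± 0.47 and MAD_Dr_004_148407-1 -5.21 ± 0.42.

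Without added hormone, MO1 changed 1213 probes, 805 higher and 408 lower than in SC-MO, in the comparison that asks what lowering both isoforms does. The largest rises were at A_15_P118741, 5.18 ± 0.42 (adjusted p = 1.73e-07), and LOLS02025, 5.14 ± 0.34 (adjusted p = 1.07e-08). The end of LOLS02025 matches the start of A_15_P118741 but for a mismatch, so both can read the same transcript. A_15_P118741 stood at -4.49 ± 0.83 (SD, n = 3) in SC-MO/veh and at 0.69 ± 0.21 in MO1/veh. The largest falls were -2.90 ± 0.15 at LOLS02872 (adjusted p = 4.53e-10) and -2.79 ± 0.15 at LOLS10248 (adjusted p = 7.02e-10), and LOLS02872 read 0.37 ± 0.08 in SC-MO/veh, -2.53 ± 0.15 in MO1/veh and 1.07 ± 0.06 in MO2/veh. MO1/veh and SC-MO/veh shared no slide, and 271 probes were higher and 70 lower with slide as a fixed block, where the median size of the change over the 1213 was 0.76, against 0.75 without it. The 408 lower probes were 268 with Agilent's ratio. They were 213 without SC-MO/veh replicate 1 and 200 without SC-MO/veh replicate 2. Without MO1/veh replicate 1, 2 or 3 they were 207, 257 and 163. The count of both directions fell to 714 without SC-MO/veh replicate 1, 652 without SC-MO/veh replicate 2, 697 without MO1/veh replicate 1 and 629 without MO1/veh replicate 3.

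MO2 gave the broadest change, 4870 probes higher and 3686 lower than in SC-MO in vehicle, of which 696 and 447 changed at least 2-fold. MAD_Dr_004_182416-1 rose by 5.82 ± 0.60 (adjusted p = 4.1e-06) and LOLS01932 by 5.56 ± 0.57 (adjusted p = 4.22e-06). The end of LOLS01932 resembles the start of MAD_Dr_004_182416-1, so these too can read the same transcript. The falls at A_15_P101085, -3.84 ± 0.83 (adjusted p = 0.00798), and MAD_Dr_004_122352-1, -3.09 ± 0.59 (adjusted p = 0.00311), were less precise, and both calls were lost with slide as a fixed block, at -3.72 ± 1.17 and -3.36 ± 0.81. A_15_P101085 read 0.40 ± 1.80 (SD, n = 3) in SC-MO/veh, and its change of -2.80 without SC-MO/veh replicate 2 missed the threshold. The MO2 and MO1 lists shared 670 higher and 250 lower probes, where independent lists would share 26.6 and 10.19. Both comparisons used the same SC-MO/veh arrays. Their changes had r = 0.662 over all tested probes, and simulated unchanged groups against shared arrays gave r = 0.501. The covariance was 0.0511, and 0.0228 in the simulation. Part of the overlap may come from the shared arrays, which were too few to be split. Slide 3 held 1 array of each group. With those 2 arrays left out of the fit 2359 probes were called higher and 1479 lower, of which 95.9% and 95.7% had that direction on slide 3, with median differences of 0.65 and -0.55. With slide as a fixed block 1240 probes were higher and 663 lower, and the median size of the change over the 8556 was 0.63 without and with it. The count fell to 3967 without SC-MO/veh replicate 2, 4901 without MO2/veh replicate 1 and 4744 without MO2/veh replicate 2.

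Against this similarity, 26 probes were lower with MO1 and higher with MO2, where independent lists would share 13.5. The 26 fell into 12 overlap groups, so they are not 26 separate cases. The probes lower with MO1 and higher with MO2 had median brightness of 12.28 and 11.48 (log2), against 8.73 over all tested probes. The value of 13.5 takes neither into account, so the excess over it decides nothing. LOLT00996 (60-mer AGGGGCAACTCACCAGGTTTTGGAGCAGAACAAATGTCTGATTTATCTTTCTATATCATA), singled out after its values were seen, was -2.10 ± 0.16 (log2, SE) with MO1 (adjusted p = 5.73e-08) and 3.75 ± 0.16 with MO2 (adjusted p = 5.82e-11). Its group means were -1.84 ± 0.21 (SD, n = 3) in SC-MO/veh, -3.94 ± 0.26 in MO1/veh, 1.91 ± 0.15 in MO2/veh and -2.18 ± 0.10 in zGRb mRNA/veh. The other way, higher with MO1 and lower with MO2, went 3 probes, where independent lists would share 20.1.

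**Figure D4:**
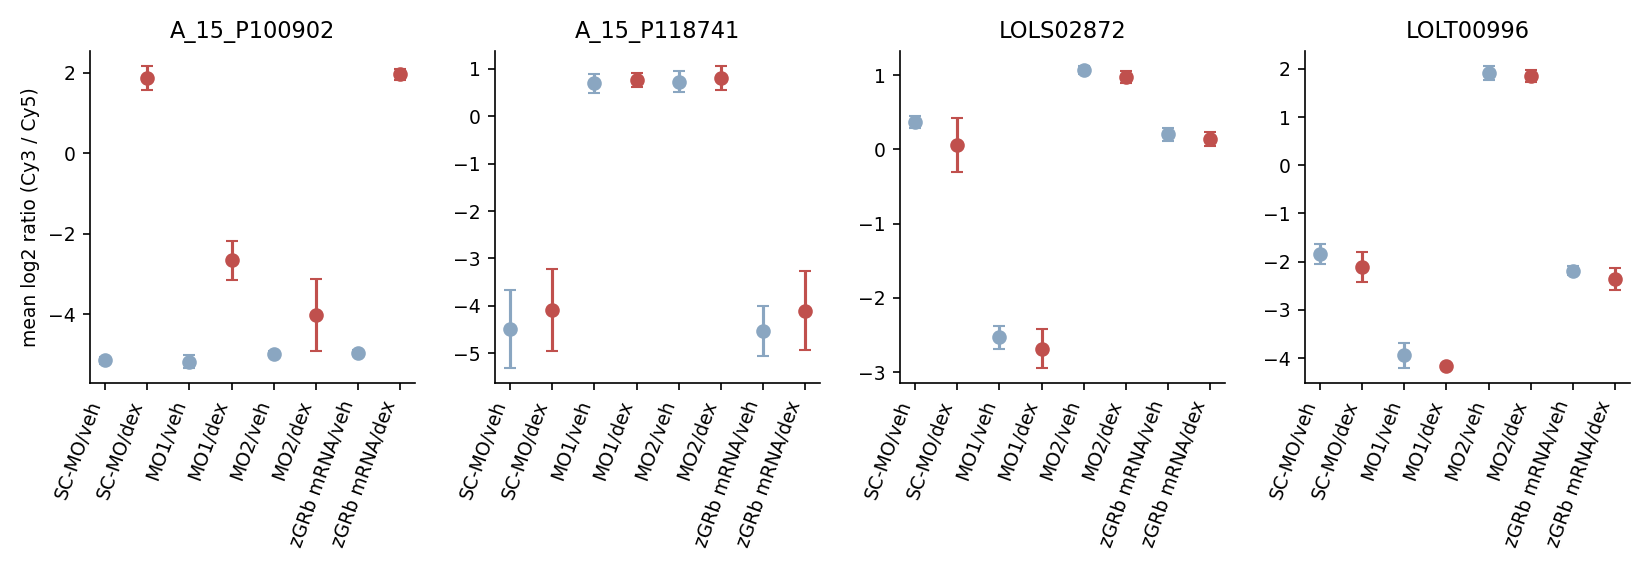
Mean log2 ratio (y axes, Cy3 over Cy5, each panel with its own scale) of 4 probes in the 8 groups (x axes), with bars of 1 SD over 3 arrays. A_15_P100902 rose with dex in SC-MO and zGRb mRNA, A_15_P118741 stood near 0.7 in the MO1 and MO2 groups and near -4 in the others, and LOLS02872 and LOLT00996 were lowest in MO1 and highest in MO2.

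No probe passed the test between embryos given zGRb mRNA and SC-MO embryos in vehicle. Limma called 0 probes, with 6441 at an unadjusted p under 0.05 and a smallest adjusted p of 0.264, and 3 probes passed when only these groups were fitted. The 6441 were fewer than the 7378 expected with no effect, so the count of 0 does not show that a change was absent. A_15_P118741 differed by -0.04 ± 0.42, and A_15_P100902 by 0.17 ± 0.29. The correlation of this comparison with MO1 against SC-MO was 0.361 and with MO2 against SC-MO 0.214, both under the value of 0.50 that shared arrays alone gave in the simulation. The differences on slides 1 and 2, which held an array of each group, correlated at -0.006 and 0.039 with those fitted without the 2 arrays of that slide.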

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

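The tests of channel identity, of the probes picked in zGRb mRNA, of the level in vehicle and of the 26 probes on the dex arrays, and the free redraw of labels, were chosen only after the results were seen.

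The response to dexamethasone differed from that in SC-MO at 186 probes in MO1 and at 245 in MO2, by the test of the difference itself. Most of these probes responded less with the morpholino. Named among them were A_15_P120582 (-4.68) and LOLS12843 (-4.60) for MO1, and A_15_P100902 (-6.05) and MAD_Dr_004_148407-1 (-6.004) for MO2. Of these, LOLS12843 and MAD_Dr_004_148407-1 can read the same transcript. In the other direction 6 probes differed for MO1 and 6 for MO2, and those named were LOLS03383 (1.39) and MAD_Dr_004_156884-1 (1.35) for MO1 and MAD_Dr_004_102399-1 (1.37) and MAD_Dr_004_501114-1 (1.36) for MO2. Both sets of 6, with 5 probes in common, were among those that fell with dex in SC-MO. Both differences subtract the response of the same SC-MO arrays, so this overlap is no separate evidence. With slide as a fixed block 0 probes were higher for either difference and the 4 calls were lost, at 1.33, 1.22, 1.58 and 1.39, and that of MAD_Dr_004_501114-1 was lost under 14 of 34 alternatives.

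The 3 technical explanations tested for the smaller responses in MO1 and MO2 each met a value that argues against it. Picking the probes by their change in SC-MO cannot be the whole cause, since probes picked in zGRb mRNA still responded more in SC-MO than in MO1, with medians of 0.92 and 0.12 that lie 0.79 apart and a median difference between the responses of -0.82. A difference between slides 4 to 6 and slides 1 to 3, estimated from the MO2 and zGRb mRNA arrays, had a median of 0.029 over the risers (quartiles -0.05 and 0.10), far below their change of 1.04. Over the fallers its median was -0.071, in the direction of their change of -0.94. Across probes it correlated at 0.19 with dex in SC-MO and at -0.114 with MO1 against SC-MO in vehicle, so a small part from slide is not excluded. A level already raised in vehicle-treated MO1 embryos would need a shift that was not seen, as the median difference between MO1/veh and SC-MO/veh over the zGRb mRNA risers was 0.017. A loss of receptor signalling, as the design names for MO1, is one biological hypothesis that may be consistent with the value of 0.79, and it stays open.

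When dex and vehicle labels were redrawn within each injection, 14 of 100 splits gave as many probes as the 186 of MO1, with 908 in the highest other split. For MO2 13 of 100 gave as many as the 245, with 382 in the highest other, and for zGRb mRNA all 100 reached its count of 0, with 146 in the highest other. This redraw cannot decide on chance. A split that keeps the dex and vehicle labels of SC-MO, or exchanges both, leaves the response of SC-MO in the contrast, and all 13 such splits gave as many for MO1 and for MO2, while a count of 0 is reached by any split. The split with 908 did not keep the labels of SC-MO, and a count so far above the real one points to a structure of the samples. A free redraw of the 12 arrays, run second, gave 9 and 7 of 100 splits with as many, and highest other counts of 9488 and 5053. It decides no more, since it moves the differences between injections into the contrast. For zGRb mRNA all 100 free splits reached 0, with 1934 in the highest other.

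For the test over the 8 groups, 1 of 100 splits, the real one, gave 13716 probes and the highest other 37. For dex over all 4 injections 1 of 100 gave 953 and the highest other 2. Both redraws argue against chance where arrays can be exchanged freely. Each dex array, however, correlated with 1 vehicle array of its injection at 0.495 to 0.784. The redraws broke these links, so they do not exclude chance among linked arrays. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real counts and the highest others were 726 and 1 for dex in SC-MO, 3 and 0 for dex in MO1, 864 and 1 for dex in zGRb mRNA, 1213 and 0 for MO1 in vehicle and 8556 and 0 for MO2 in vehicle, and only 1 of 10 splits, the real one, was as large in each. For dex in MO2 and zGRb mRNA in vehicle the real count and the highest other were both 0, so 10 of 10 were as large.

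The signal that follows the groups lay in the channel labelled as the common reference. Of the probes past the F-test, 99.3% varied more in Cy3, which is what a sample in Cy3 would give. Cy3 also varied more over all tested probes (median SD 0.245 against 0.131), so this share alone decides little. A sample in Cy5, as labelled, is argued against by the Cy5-only change of the SC-MO dex risers, 0.013, beside 1.07 in Cy3. Unequal noise of the dyes is argued against by 9207 probes past the F-test in Cy3 alone, with 2 in the highest of 20 regroupings. Whether the dye labels were exchanged when the arrays were hybridised or when they were described stays open, and no biological explanation was tested.

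In vehicle, 26 probes were lower with MO1 and higher with MO2, with medians of -2.44 and 0.77. The SC-MO/veh arrays were shared by both comparisons, and a deviation in them moves both the same way, so it cannot open the gap between MO1 and MO2. It would also move the comparison of zGRb mRNA with SC-MO in vehicle, which had a median of -0.051 over the 26. These values argue against a deviation of the shared arrays as the cause for the 26 as a set. On the dex arrays all 26 were lower in MO1/dex and higher in MO2/dex than in SC-MO/dex, with medians of -2.36 and 0.90. Each dex array correlated with a vehicle array of its injection at 0.495 to 0.784, so the dex arrays are no separate check. The simulation of unchanged groups decides nothing here, as it gave 0 probes called in both comparisons in either direction. Whether the probes read overlapping pieces of 1 transcript cannot be told from sequence overlap, as the 26 fell into 12 overlap groups and the largest held 7. Of the 26, 20 had IDs of a family (LOL and a number) that made up 2.57% of tested probes, and the longest run of consecutive numbers was 7. Probes tiled along a few transcripts are a candidate explanation that 7 in 1 group leaves open, and an effect of isoform choice, which the design names, was not tested.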

How the results depend on the processing

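The dyes as labelled and 1 probe per overlap group were alternatives chosen after the data were seen. All 12 counts of called probes stayed within 1.5 times, with their directions, with no background subtraction, with Agilent's ratio, with the authors' value table, with no filter, with probes well above background on all 24 arrays, with slide as a random block and with 1 probe per overlap group. Scaling between arrays moved only dex in MO1, to 0. With the dyes as labelled the direction turned everywhere, by construction, and the filter lay on Cy5 (131881 probes), with 949 probes for dex over all 4 injections, 710 for dex in SC-MO, 3 for dex in MO1, 845 for dex in zGRb mRNA, 1250 and 8795 for MO1 and MO2 in vehicle, and 187 and 248 for the differences of MO1 and MO2.

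Slide as a fixed block gave 8327 probes for the F-test, 258 for dex in SC-MO, 358 for dex in zGRb mRNA, 341 and 1903 for MO1 and MO2 in vehicle, and 23 and 51 for the differences of MO1 and MO2. The correlations of responses became -0.325 (main 0.138) for dex in SC-MO and MO1, -0.283 (main 0.008) for SC-MO and MO2, 0.675 for SC-MO and zGRb mRNA, 0.699 for MO1 and MO2 in vehicle and 0.455 for MO1 and zGRb mRNA in vehicle. Dex in SC-MO sets slides 4 to 6 against slides 1 to 3, and dex in MO1 sets slides 1 to 3 against slides 4 to 6. An error in the fitted slide terms thus enters these 2 responses with opposite signs, and those of SC-MO and MO2 in part so. The negative values therefore do not show opposed responses. How much of the reversals this layout gives was not tested. Agilent's ratio gave 0.062, -0.030 and 0.361 for dex in SC-MO with MO1, MO2 and zGRb mRNA, and 0.602 and 0.287 for MO2 with MO1 and with zGRb mRNA in vehicle. Probes bright on all 24 arrays gave 0.202 for SC-MO and MO1 and 0.642 for SC-MO and zGRb mRNA. Why these correlations moved was also not tested. The slide test within groups called 0 probes (limma; 4632 at an unadjusted p under 0.05), and 0 with Agilent's ratio.

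Fitting only the groups compared, which leaves fewer arrays for the spread, gave 270 probes for dex in SC-MO, 0 for dex in MO1, 360 for dex in zGRb mRNA, 351, 2447 and 3 for MO1, MO2 and zGRb mRNA in vehicle, and 83 for the difference of MO1. Leaving out each array in turn gave 10986 to 14824 for the F-test, 798 to 989 for dex over all 4 injections, 466 to 754 for dex in SC-MO, 0 to 4 for dex in MO1, 0 to 0 for dex in MO2, 627 to 925 for dex in zGRb mRNA, 629 to 1416, 3967 to 9377 and 0 to 1 for MO1, MO2 and zGRb mRNA in vehicle, and 139 to 192, 184 to 246 and 0 to 0 for the 3 differences. The 1 probe for zGRb mRNA in vehicle came without MO2/dex replicate 1 or zGRb mRNA/veh replicate 3.

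The replicate block gave 859 for dex over all 4 injections, 638 for dex in SC-MO, 763 for dex in zGRb mRNA, 910 and 7082 for MO1 and MO2 in vehicle, 163 and 222 for the differences. The block tests only the replicate numbers. Deviations of same-numbered arrays from the group means correlated at -0.059 on average, 22 of 84 pairs exceeded 0.1, and 3 of 12 dex arrays correlated best with the vehicle array of their number. Each dex array correlated with 1 vehicle array of its injection at 0.495 to 0.784 and with the others at 0.047 or less, a structure that no fit here took into account.

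Of 1084 values of named probes under the alternatives, 1026 kept their side of the threshold, 58 no longer passed it, and 0 turned direction. Of the 58, 14 were MAD_Dr_004_501114-1 in the difference of MO2, 13 MAD_Dr_004_171325-1 with dex in zGRb mRNA, 11 MAD_Dr_004_159104-1 with dex in SC-MO, 4 and 5 the 2 probes named for dex in MO1, and 3 A_15_P101085 with MO2 in vehicle. The alternatives added later are not among these values. Simulated log2 changes of 0.5 were recovered at 18% for dex in SC-MO, the only contrast in which recovery was simulated. Counts of 0 in other contrasts do not exclude changes of that size or larger ones. With dex in MO2, A_15_P100902 read 0.96 ± 0.29 and was not called.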

Other observations

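The contrast of MO2 with MO1 in vehicle was chosen after other results were seen. It called 559 probes higher and 292 lower with MO2, with no SC-MO array in the difference.

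Few of the probes that responded to dexamethasone were called for the morpholinos in vehicle, though more were higher than independent lists would share. Of the 676 risers of SC-MO, 16 were higher and 0 lower with MO1 in vehicle, where independent lists would share 3.69 and 1.87. With MO2 52 were higher and 20 lower, where independent lists would share 22.3 and 16.9. Called probes were brighter than the tested probes as a whole, which the independent lists do not take into account. These comparisons also share the SC-MO/veh arrays. Of the 817 risers of zGRb mRNA, picked without these arrays though 572 of them also rose in SC-MO, 16 were higher and 2 lower with MO1, where independent lists would share 4.46 and 2.26, and 55 were higher and 30 lower with MO2, where they would share 27.0 and 20.4. The median change of the 676 risers in vehicle was 0.03 with MO1, 0.08 with MO2 and -0.01 with zGRb mRNA.

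The risers of dex in SC-MO were brighter than the tested probes as a whole, with a median mean brightness of 10.51 against 8.73 (log2). The fallers were brighter still, at 12.65. Their median GC content was 41.7% and 39.2%, against 43.3% over all tested probes.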
